A study of Mus musculus with 14 samples.

How the data were processed

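RNA was measured in 14 libraries of CD4+ Foxp3-reporter+ T cells sorted from lymph nodes of BALB/c mice at postnatal day 35, 7 wild type and 7 Il1rn-/-. Per the labels' protocols, RNA was extracted with the Qiagen RNeasy Micro kit and libraries were made with Smart-Seq2, a method for low input. Transcripts were quantified with Cuffquant 2.2.1, per the labels' protocols. The submitters' processing notes name BWA, TopHat2 2.0.10, Cufflinks 2.2.1 and Cuffnorm. The genome build, the annotation, the handling of strand and of reads shared between genes, and the tool that made the deposited values are not given in the sources used here, so no coordinates are reported.

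The values deposited by the authors are log2 CPM, reads scaled to a common library size and logged with a small prior count, in 1 table of 14449 genes with Entrez identifiers and symbols, 165 of them without a symbol. All 14 libraries share a lowest value of -3.58, which stands for 0 reads. The steps above it are evenly spaced on the linear scale, and whole reads were recovered from them, with 100% of values within 0.001 of a whole number and the farthest at 3.9e-08. Recovered reads were used for depth and a test of it, for the reads of single genes, for the calls of Y-linked transcripts and for limma voom. The log2 values were used for every main test. Depth is the recovered reads in the genes of the table, which were 952021 to 3756559 per library. Low reads limit precision for weakly expressed genes, and reads without molecular identifiers are not independent molecules.

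Genes with a CPM over 1 in at least 3 libraries were tested, which left 12329. The main model was limma 3.58.1 in R 4.3.3 with an intensity trend, genotype and the letter of the sample title as terms, two-sided moderated statistics and Benjamini-Hochberg adjustment at 0.05. A model with 4 groups of genotype and letter gave the contrasts within set a, within set b and their difference. Gene lists were written before the data were examined, as were the main models, the rule for named genes and most alternatives. Of 30 lists, 27 had at least 5 tested genes. They were tested with limma's camera at a preset correlation of 0.01 and at an estimated one, with fry, and with an exact two-sided permutation of the list mean between libraries within letters or within library groups, each adjusted over the lists. Other work used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The steps were tested on simulated data with known changes.

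The named genes were a fixed set (Il1rn, Foxp3, Il2ra, Ctla4, Il1r1, Il1r2, Tnfsf11, Il17a, Ccr6 and 1 gene not reported here), up to 8 genes per direction with the largest change among those that passed, up to 4 genes per list with the smallest p, and up to 6 genes for the difference between sets. Where fewer than 5 genes passed in a direction, the 8 came from the smallest unadjusted p at a mean log2 CPM of 2 or more and the same sign in both sets, and are reported as not passing. Predicted genes and antigen receptor segments were left out of those 8.

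Alternatives covered the filter, the prior count, scaling between libraries, the letter term, a block by replicate number, the variance model, library weights, a fold threshold, each library left out, each set alone and the set tests. Chosen after seeing the data were the library group found from the correlations (shallow or deep) as covariate, the same with Y-linked transcripts, subsets of libraries, and limma voom on the recovered reads. Sequence shared between genes was measured by exact matches of 32 bases between reference transcripts, for 91.9% of tested genes. Libraries were called positive for Y-linked transcripts from 20 reads. No library was left out of the main tests.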

Results

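The targeted gene could not be used to check the genotype labels, because Il1rn is not among the genes of the table analysed here. Il1rn encodes the IL-1 receptor antagonist, the secreted protein that keeps IL-1 from its signalling receptor. The profiles came from CD4+ Foxp3-reporter+ regulatory T cells sorted from lymph nodes of BALB/c mice at postnatal day 35, 7 libraries from wild-type and 7 from Il1rn-/- animals. The sample titles divide the libraries into a set a (3 wild-type, 3 Il1rn-/-) and a set b (4 wild-type, 4 Il1rn-/-), and the labels do not explain the letters. Nothing in the labels says that the libraries came from separate animals, so every p-value here measures only the spread between libraries.

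Reads in the genes of the table numbered 3355033, 3019628 and 3522049 in wild-type 1-a to 3-a and 3325760, 3449410 and 3756559 in Il1rn-/- 1-a to 3-a. They numbered 2151760, 1968599, 952021 and 2241441 in wild-type 1-b to 4-b and 2219941, 2332469, 3618474 and 2755990 in Il1rn-/- 1-b to 4-b. By their correlations the libraries fell into 2 groups that did not follow the letters. A shallow group of 6 libraries (wild-type 1-b to 4-b, Il1rn-/- 1-b and 2-b) had 384360 to 905988 reads outside Rn45s, and a deep group of 8 libraries (3 wild-type, 5 Il1rn-/-) had 1654868 to 2805693. The ribosomal RNA precursor gene Rn45s took 59.6% to 65.8% of the reads in the shallow group and 20.3% to 39.95% in the deep group. The mitochondrial ribosomal RNA gene mt-Rnr2 took 2.82% to 4.01% and 8.68% to 16.2% of the remaining reads, so both shares separated the groups without overlap. Pearson's r across genes, which are not independent replicates, was 0.878 to 0.916 within the shallow group, 0.910 to 0.941 within the deep group and 0.821 to 0.866 between them. Il1rn-/- 3-b and 4-b reached 0.910 to 0.935 with set a and 0.824 to 0.859 with the rest of set b. Because the deep group held more Il1rn-/- libraries, the genotype differences of the named genes and lists are also given with this grouping in place of the letter where stated, a covariate chosen after seeing the data. Y-linked transcripts were found in 4 deep libraries, wild-type 1-a and 2-a and Il1rn-/- 3-b and 4-b, so within each set they were in 1 genotype only.

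**Figure D1:**
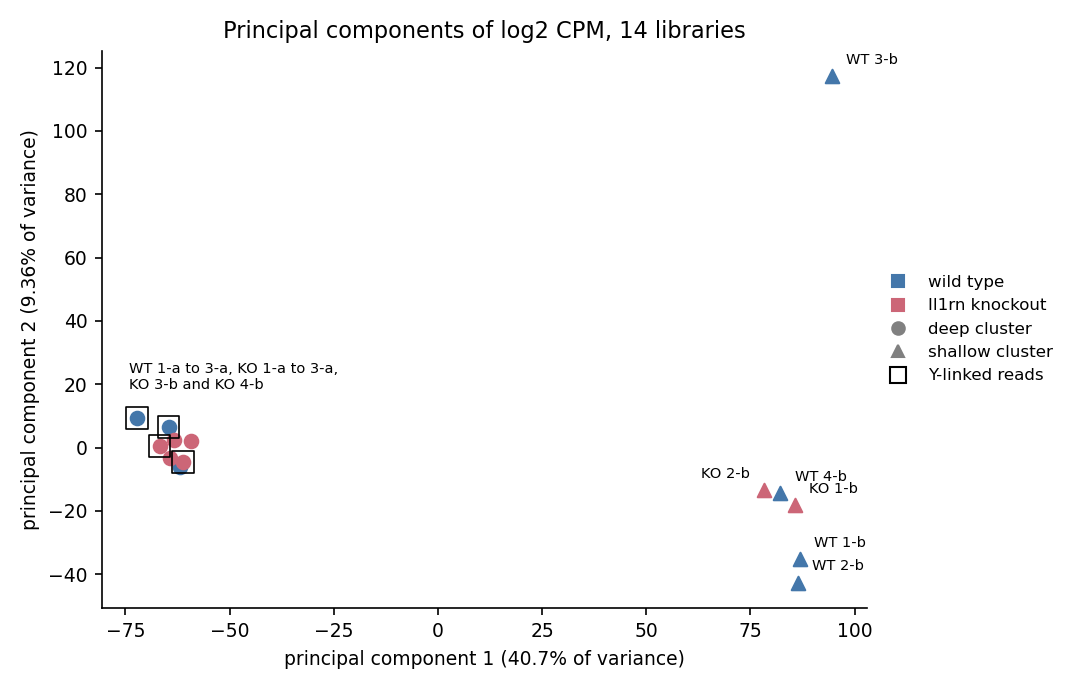
Principal components of the log2 CPM values of the 14 libraries, 1 point per library, with the first component (40.7% of the variance) on the horizontal axis and the second (9.36%) on the vertical axis. The first component separates the 6 shallow libraries from the 8 deep ones, and Il1rn-/- 3-b and 4-b lie with set a.

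The first question was whether regulatory T cells of arthritis-prone Il1rn-/- mice differ in their transcripts from wild-type cells. Foxp3, which specifies the lineage, was at 8.56 ± 0.32 log2 CPM in wild type and 8.59 ± 0.24 in Il1rn-/- (mean ± SD, n = 7 each), a log2 difference of 0.03 with a 95% confidence interval of -0.31 to 0.37. Il2ra, the high-affinity subunit of the IL-2 receptor, differed by -0.22 ± 0.14 (estimate ± SE here and below), and by -0.01 with the library group as covariate. Ctla4, the inhibitory receptor for CD80 and CD86, differed by 0.20 ± 0.29, and by -0.11 with that covariate. Il1r2, the decoy receptor that binds IL-1 without signalling, was at 5.41 ± 0.44 and 5.52 ± 0.42 log2 CPM (SD, n = 7 each) and differed by 0.10 ± 0.18, or by -0.09 with the covariate. The signalling receptor Il1r1 had 0 to 25 reads per library and 0 reads in 8 of the 14, so a difference in it was not detectable at this depth. Tnfsf11, which encodes the osteoclast differentiation factor RANKL, had 7 to 76 reads and differed by -0.36 ± 0.51, with an interval of -1.43 to 0.72, and by -0.05 with the library group as covariate. Ccr6, a chemokine receptor found on IL-17-producing and other T cells, differed by 0.25 ± 0.23 and by -0.12 with the library group as covariate. Il17a is not among the genes of the table.

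No gene passed the threshold in this comparison. Of 12329 genes, 0 were higher and 0 lower in Il1rn-/- at an adjusted p under 0.05 by limma, 679 had an unadjusted p under 0.05 where chance alone gives 616, and limma voom on recovered reads called 0 (733 unadjusted). The smallest adjusted p by limma was 0.787. With the library group as covariate 0 genes passed and 303 had an unadjusted p under 0.05. The median standard error was 0.287 over all tested genes and 0.188 over the 5227 genes with a mean log2 CPM of 4 or more.

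The genes with the smallest unadjusted p are given as the leading ones that did not pass, all at an adjusted p of 0.787 by limma. Fam214a was at 3.71 ± 0.33 log2 CPM in wild type and 4.51 ± 0.38 in Il1rn-/- (SD, n = 7 each), a difference of 0.80 ± 0.18 that was 0.66 with the library group as covariate, and all 7 Il1rn-/- libraries lay above the wild-type mean. Casp1, the protease that matures IL-1β and IL-18, was at 3.47 ± 0.94 and 4.49 ± 0.54 log2 CPM and differed by 1.01 ± 0.27, with 7 of 7 Il1rn-/- libraries above the wild-type mean. Its difference was 0.65 with the library group as covariate. The 3 deep wild-type libraries also lay above the wild-type mean, for Fam214a at 3.75 to 4.24 and for Casp1 at 4.01 to 4.75. The 4 shallow wild-type libraries lay below it for Casp1, at 2.56 to 3.08. Other positive differences were 0.99 ± 0.25 for the mitochondrial protease gene Spg7, 0.75 ± 0.21 for the interferon-inducible Samd9l, 0.54 ± 0.15 for the calcium-binding Rcn1, 0.76 ± 0.21 for the apoptosis regulator Bfar, 1.24 ± 0.35 for the Aurora kinase cofactor Bora and 0.98 ± 0.29 for the mannosyltransferase Alg2. Under the library group as covariate Spg7 came to 0.68, Samd9l to 0.32, Rcn1 to 0.40, Bfar to 0.63, Bora to 0.84 and Alg2 to 0.60.

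Among the negative differences, the zinc finger transcription factor gene Rreb1 was at 4.26 ± 0.24 log2 CPM in wild type and 3.70 ± 0.16 in Il1rn-/- (SD, n = 7 each). Its difference was -0.56 ± 0.17, and -0.50 with the library group as covariate. All 7 Il1rn-/- libraries lay below every wild-type library. The difference was -0.58 ± 0.17 for the dynein-associated Nudc, -1.12 ± 0.33 for the cyclin-dependent kinase subunit Cks2, -0.63 ± 0.19 for the chaperone Hsp90aa1 and -0.83 ± 0.26 for the MYC partner Max. It was -0.68 ± 0.22 for the forkhead factor Foxk1, -0.85 ± 0.27 for the RNA methyltransferase Ftsj1 and -1.08 ± 0.36 for Tmem223. With the library group as covariate Nudc came to -0.35, Cks2 to -0.66, Hsp90aa1 to -0.36, Max to -0.40, Foxk1 to -0.48, Ftsj1 to -0.62 and Tmem223 to -0.57. Genes with near-identical copies or pseudogenes, Hsp90aa1 and Cks2 among them, are uncertain, because the counting is not stated to handle shared reads or strand.

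**Figure D2:**
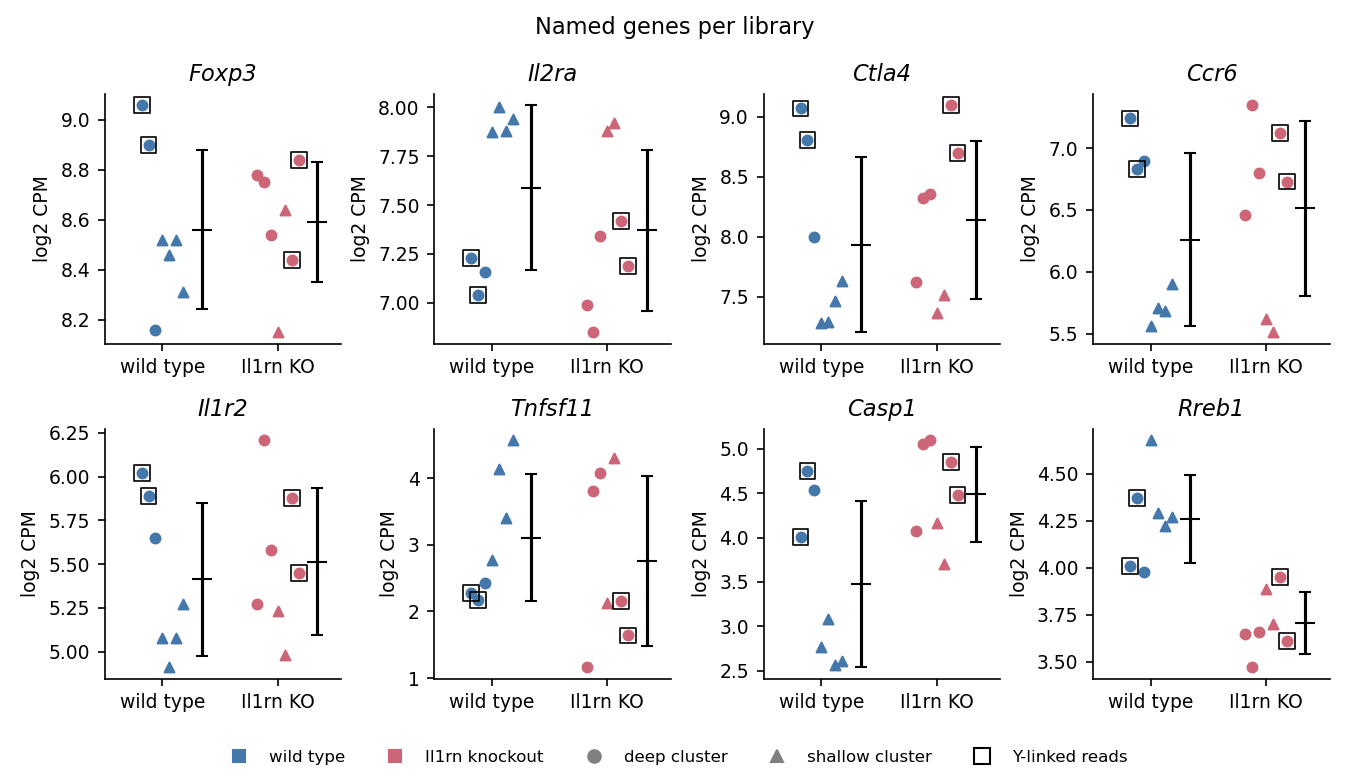
Log2 CPM (vertical axes) of 8 genes in each library by genotype (horizontal axis), with circles for deep and triangles for shallow libraries, frames for libraries with Y-linked reads, and bars for the mean and SD of 7 libraries per genotype. Foxp3 means are 8.56 and 8.59, Casp1 means are 3.47 and 4.49, and no gene passed the adjusted threshold.

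Transcripts induced by interferon formed 1 of the 2 gene lists called. Of 40 interferon-stimulated genes tested, 33 had positive and 7 negative differences, with a median log2 difference of 0.32, and the mean over the list was 4.17 ± 0.32 log2 CPM in wild type and 4.55 ± 0.38 in Il1rn-/- (SD, n = 7 each). The immunity-related GTPase gene Iigp1 differed by 0.72 ± 0.22, the guanylate-binding protein gene Gbp2 by 0.37 ± 0.15 and the antiviral Oas1a by 1.76 ± 0.73. Iigp1 came to 0.37, Gbp2 to 0.30 and Oas1a to 0.97 with the library group as covariate. Of the list's genes, 0 passed over all genes and 0 adjusted over the list alone, with 8 at an unadjusted p under 0.05. The list mean was above the wild-type mean in 6 of 7 Il1rn-/- libraries. By limma's camera with a preset correlation the list was called higher at an adjusted p of 0.000355. With an estimated correlation the call was lost (p = 0.161 by limma's camera). The exact two-sided permutation p of the list mean was 0.0857 with libraries exchanged within letters and 0.0798 within library groups. The call by camera was also lost without Il1rn-/- 3-a (median 0.24, adjusted p 0.122), in set b alone (0.22, adjusted p 0.417), in the shallow libraries alone (0.25, adjusted p 0.341) and in the 10 libraries without Y-linked transcripts with the library group as covariate (0.18, adjusted p 0.109).

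Genes of oxidative phosphorylation were the other list called. Of 51 genes, 40 had negative and 11 positive differences, with a median of -0.16 and an adjusted p of 0.000355 by limma's camera with a preset correlation. The call was lost with an estimated correlation (p = 0.296 by limma's camera). With the library group as covariate the median was 0.01 and the adjusted p 0.961, and within the 8 deep libraries the median was 0.17, the opposite direction. The call was also lost without Il1rn-/- 4-b (adjusted p 0.120) and in set a alone (median 0.06, adjusted p 0.883). With the library group as covariate camera called the cell cycle genes lower instead (median -0.14, adjusted p 0.00795), a call lost with an estimated correlation (p = 0.389) and with Y-linked transcripts as a further covariate (adjusted p 0.338). In the 10 libraries without Y-linked transcripts camera called these genes in the opposite direction (median 0.20, adjusted p 0.00289), a call also lost with an estimated correlation (p = 0.266 by limma's camera).

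The lists closest to the study's subject were not called. Of 9 factors that promote osteoclasts 4 differed positively and 5 negatively, with a median of -0.02, and the 8 factors that restrain osteoclasts had a median of 0.23, which was -0.11 with the library group as covariate. Treg identity genes (24 tested) had a median of 0.03, effector Treg genes (30) -0.02, genes of naive and central T cells (20) -0.05, Th17 genes (21) 0.01, Th1 genes (16) 0.14, Th2 genes (8) -0.14 and follicular genes (11) 0.02. The effector Treg median was -0.14 with the library group as covariate (11 positive, 19 negative). With library weights camera called that list lower (median -0.11, adjusted p 0.0448), a call lost with an estimated correlation (p = 0.410 by limma's camera). Means were opposite in sign to the medians for Treg identity (-0.01), naive and central T cells (0.06) and follicular genes (-0.12). In IL-1 family signalling 13 of 19 genes differed positively, with a median of 0.08. The tally was 8 positive and 11 negative with the library group as covariate, with a median of -0.03, and in the deep libraries alone camera called the list lower (median -0.17, adjusted p 0.0185), a call lost with an estimated correlation (adjusted p 0.955 by limma's camera, 0.0387 unadjusted). Casp1 was the only gene of any list to pass adjusted over the list alone (adjusted p 0.0232 by limma, log2 difference 1.01). With the library group as covariate that adjusted p was 0.102. Casp1 was above the wild-type mean in 7 of 7 Il1rn-/- libraries, but also in the 3 deep wild-type ones. Il18, the cytokine that caspase-1 also processes, differed by -1.92 ± 0.71 at a mean log2 CPM of -0.45, and Il1rl1, the IL-33 receptor, by -0.46 ± 0.28.

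NF-κB targets had a median of 0.18 over 27 genes, with 22 positive, and -0.01 with the library group as covariate. Stress and immediate early genes (28) had a median of 0.26, and -0.07 with that covariate. Medians were 0.05 for the TNF and TNF receptor families (25 genes), -0.05 for chemokine receptors and homing genes (28), 0.12 for cytokine receptors and STAT genes (36) and -0.01 for the TGF-β pathway (16). They were -0.04 for the cell cycle (40), 0.04 for glycolysis (25, mean -0.01), -0.06 for cholesterol and lipid synthesis (29) and -0.08 for the early response to the antigen receptor (23). Markers of other cells had medians of -0.06 for B cells (13), -0.75 for plasma cells (5), 0.14 for monocytes and macrophages (12), -0.25 for dendritic cells (11) and -0.16 for CD8 T and NK cells (7). The B cell median was -0.30 with the library group as covariate, and with Y-linked transcripts added camera called that list lower (median -0.39, adjusted p 0.0312), a call lost with an estimated correlation (adjusted p 0.919). Camera called the plasma cell list lower in the deep libraries alone (median -1.69, adjusted p 0.0185), a call lost with an estimated correlation (adjusted p 0.955 by limma's camera). The mean of the monocyte and macrophage markers was -0.10, opposite in sign to their median, and their median was -0.11 with the library group as covariate. Medians that also changed sign with that covariate came to 0.05 for naive and central T cells, -0.04 for Th17, -0.07 for follicular genes, 0.04 for the TGF-β pathway and 0.01 for the early response to the antigen receptor. Lists for neutrophils, stromal and endothelial cells, and red cells and platelets had 3, 2 and 4 tested genes, too few for the test, with medians of 0.39, -0.19 and 1.47. Of the 27 lists tested, limma's camera with an estimated correlation called 0, as did fry for a shared direction, fry for change in either direction and the permutation test after adjustment.

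**Figure D3:**
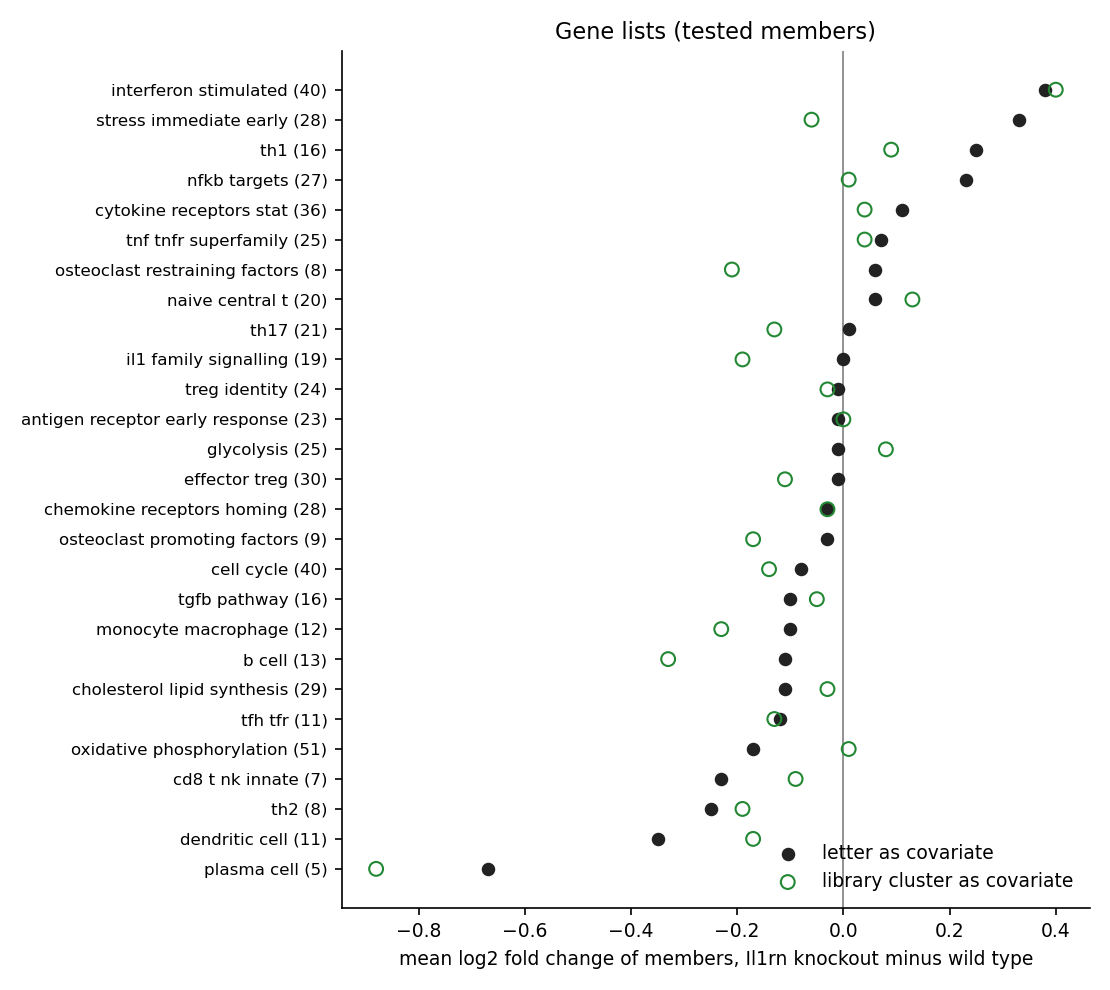
Mean log2 difference (Il1rn-/- minus wild type, horizontal axis) over the tested genes of each of the 27 lists (vertical axis), with filled points for the letter and open points for the library group as covariate. The interferon-stimulated list lies at 0.38 and 0.40, and oxidative phosphorylation at -0.17 and 0.01.

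**Figure D4:**
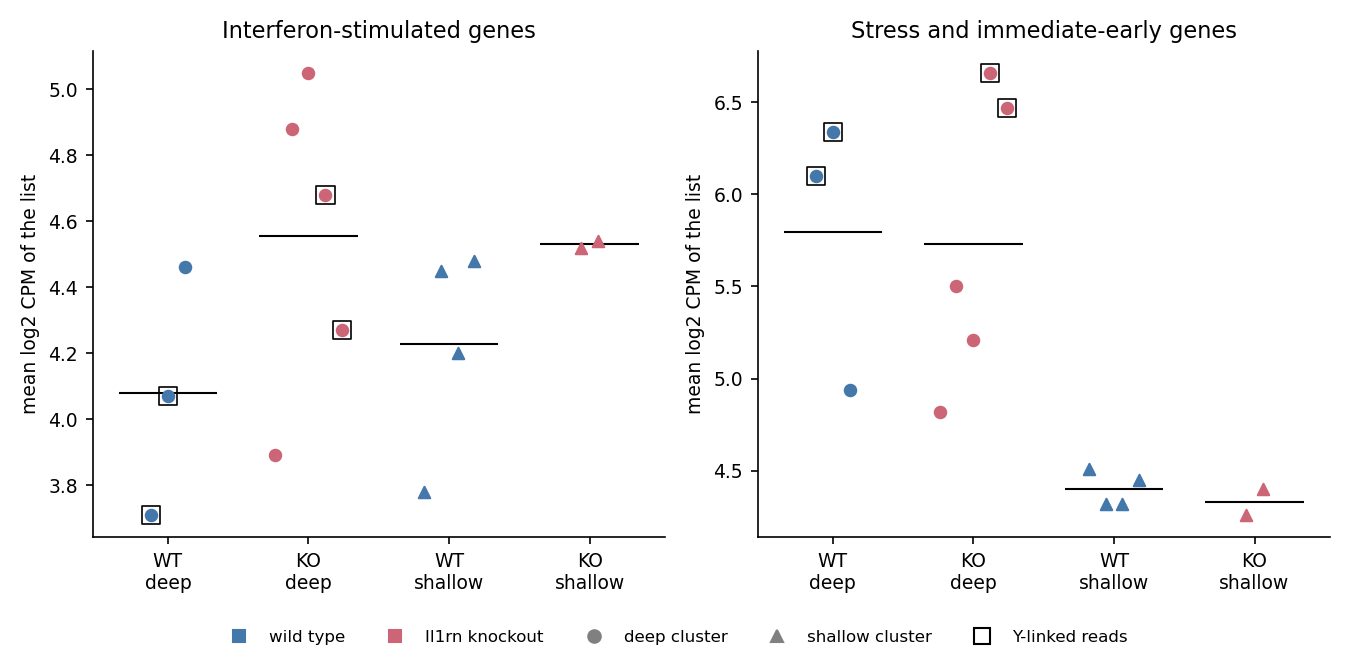
Mean log2 CPM (vertical axes) of the interferon-stimulated list and of the stress and immediate early list in each library, by genotype and library group (horizontal axis), with a line at each mean and frames for libraries with Y-linked reads. For the interferon-stimulated list 6 of 7 Il1rn-/- libraries lie above the wild-type mean of 4.17.

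The second question was whether the genotype difference was seen in both lettered sets. Casp1 differed by 0.31 ± 0.35 in set a (n = 3 per genotype) and by 1.54 ± 0.31 in set b (n = 4 per genotype), Ctla4 by -0.53 ± 0.38 and 0.75 ± 0.33, and Rora, a transcription factor of tissue Tregs and Th17 cells, by -0.36 ± 0.39 and 1.13 ± 0.33. Fam214a differed by 0.77 ± 0.29 and 0.82 ± 0.25, and Rreb1 by -0.53 ± 0.27 and -0.58 ± 0.23. Foxp3 differed by -0.02 ± 0.25 and 0.07 ± 0.22, and Tnfsf11 by 0.71 ± 0.72 and -1.16 ± 0.63. By limma 0 genes passed in set a (243 at an unadjusted p under 0.05), 0 in set b (1848 unadjusted, smallest adjusted p 0.0968) and 0 for the difference between the sets (968 unadjusted, smallest adjusted p 0.610). All 4 wild-type libraries of set b were shallow and 2 of its 4 Il1rn-/- libraries were deep, so the set b contrast carries part of the difference between the library groups. Both libraries with Y-linked transcripts were wild type in set a and Il1rn-/- in set b, so the contrasts of the sets also carry any difference that goes with these transcripts, in opposite directions. Set b counts by single libraries left out ranged from 0 to 230 genes, with 230 without Il1rn-/- 2-b, 7 without Il1rn-/- 1-b and 3 without wild-type 1-b. Across genes the log2 differences of the sets had a Pearson's r of -0.08, inside the range of -0.10 to 0.10 from 100 permutations of the genotypes, where genes are not independent replicates. Over the 5227 genes with a mean log2 CPM of 4 or more it was -0.30, inside the permuted range of -0.43 to 0.40.

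For the list means, the NF-κB targets differed by -0.18 in set a and 0.53 in set b, and the osteoclast-promoting factors by -0.76 and 0.51. Neither difference between the sets passed after adjustment over the lists (exact permutation p 0.00714 and 0.0114, adjusted p 0.154 for both). Within the deep libraries the means of these lists were higher by 0.25 and 0.59 in the 4 libraries with Y-linked transcripts than in the other 4. Among the deep Il1rn-/- libraries that contrast is also set b against set a. The library group bears on them as well, since the wild-type means were 5.72 in deep and 4.90 in shallow libraries for the NF-κB targets and 2.69 and 1.91 for the osteoclast-promoting factors. In Il1rn-/- they were 5.66 and 5.00, and 2.24 and 2.14.

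The third question was how far the lettered sets differ. With genotype in the model limma called 1046 genes higher and 1362 lower in set b, a balance that turned to 1195 and 1085 with each library centred on its median. Much of this lay between the library groups: the letter called 12 genes once the library group was a covariate. All 6 shallow libraries were of set b, so that count rests on Il1rn-/- 3-b and 4-b against the deep libraries of set a. Part of the fall to 12 may therefore be lost power. Il1rn-/- 3-b and 4-b both held Y-linked transcripts, while in set a only wild-type 1-a and 2-a did. The count of 12 thus also carries any difference that goes with these transcripts. Between the deep and shallow groups limma called 4447 genes, 2464 higher and 1983 lower in the deep libraries, a comparison that is circular because the groups were found from the same values. Genes of the cytosolic ribosome had a median deep-minus-shallow difference of -2.31, with 65 of 83 lower, and 215 pseudogenes had a median of 3.07, with 134 higher, against 0.09 for 11207 protein-coding genes. Glycolytic Pgam1 differed by -4.91 and Pgk1 by -3.38, the electron carrier gene Cycs by -3.78 and the tubulin regulator Stmn1 by -3.39. Among genes named above Il2ra differed by -0.76, Ctla4 by 1.11, Ccr6 by 1.30, Rora by 1.60, Il1r2 by 0.68 and Casp1 by 1.27. Each was past the adjusted threshold by limma.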

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

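No test of this part was chosen after its result was seen. In each genotype (n = 7) the highest and lowest library of every named gene and list mean was set against Dixon's critical value at 95%. Of 304 such tests 24 found a library far from the others, where chance alone gives about 1 in 20, or 15.2.

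Genes of T cell and Treg function were among them in single wild-type libraries. Wild-type 3-a was low in the semaphorin gene Sema4d at 7.22 log2 CPM, in the chemokine receptor Cxcr4 at 3.48 and in the proprotein convertase Furin at 1.78. The same library was high in Bfar at 5.69. The chromatin organiser Satb1 was low in wild-type 3-b at 6, as was the perforin gene Prf1 at 1.27. The TNF family ligand Tnfsf9 was low in wild-type 1-b at 0.52, and the TGF-β coreceptor Tgfbr3 was low in wild-type 1-a at 2.01. Ly6c1 at -0.11 in wild-type 1-a and Oasl2 at 0.24 in wild-type 4-b had reads in that wild-type library alone. Blk and Fscn1 had 0 reads in wild-type 1-b and Mzb1 in wild-type 2-b, each at the lowest value of -3.58. The mean of the dendritic cell markers was high in wild-type 4-b, at 4.16.

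Among Il1rn-/- libraries, 1-b was low in Bfar at 4.58 and in Tnfsf9 at -0.52, had 0 reads of the transcription factor Tox2 (-3.58), and was high in the lipid synthesis enzyme Acaca at 4.21, in the NKG2D gene Klrk1 at 1.34 and in the mean of the TGF-β pathway at 4.74. The secretory pathway factor Xbp1 was low in 3-b at 4.92, and Il12rb2, the inducible subunit of the IL-12 receptor, had 0 reads there (-3.58). The signalling adaptor Traf2 was low in 2-b at 5.62, and the carbonic anhydrase gene Car2 had 0 reads there (-3.58). These values were not tested further.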

How the results depend on the processing

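The settings with the library group or Y-linked transcripts, the subsets by library group, the omission of Il1rn-/- 3-b and 4-b, and limma voom were chosen after seeing the data. Genes higher in Il1rn-/- stayed at 0, except for 1 (Cacnb3) in the deep libraries alone and 13 in the shallow ones alone, each of the 13 with 0 reads in every shallow wild-type library and at most 5 elsewhere in that group. Genes lower stayed at 0, except for 1 with set a alone (Armc3, at most 7 reads) and 1 in the deep libraries alone (Loxl2, at most 3 reads). With single libraries left out, both stayed at 0, set a ranged from 0 to 1 (Hsph1, without wild-type 3-a), set b from 0 to 230 and the difference between sets from 0 to 0. Set b gave 6 genes and the difference between sets gave 2 (Samd11, Snord100) without the intensity trend. Set b gave 4 with the library group (Pcyt1b, Angpt2, Gpr137b-ps, Gfpt2), 1 with the library group and Y-linked transcripts, and 1 without Il1rn-/- 3-b and 4-b (Pcyt1b both times). These few genes were named after their values were seen. For all of these counts the cause was not tested.

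The letter called 4091 genes with library weights, 340 with a fold threshold (a stricter hypothesis by construction), 4462 without Il1rn-/- 3-b and 4-b, and 1355 to 3376 with single libraries left out. The count was 1355 without wild-type 2-a, 1570 without wild-type 1-a and 3376 without Il1rn-/- 4-b. Genes higher and lower in set b were 1046 and 1362, and 1195 and 1085 after median centring. The correlation of the sets across genes moved from -0.08 to -0.17 with the strict filter, -0.16 and -0.21 with a prior of 1 and 5 CPM, -0.02 with the library group, 0 with the library group and Y-linked transcripts, -0.02 without Il1rn-/- 3-b and 4-b and -0.01 by voom with the library group, and lay between -0.10 and -0.05 with single libraries left out. For the letter and the correlation the cause was not tested.

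Lists called by camera numbered 2, 5 with library weights, 4 with set a alone, 5 in the deep libraries alone, 1 in the shallow ones alone, 0 with an estimated correlation, 0 by fry, and 0 with an estimated correlation and the library group. They ranged from 1 to 6 with single libraries left out, with 6 without wild-type 3-a, 4 without wild-type 1-b, wild-type 2-b or Il1rn-/- 2-b, and 1 without Il1rn-/- 3-a or 4-b. Lists called in the direction opposite to the one reported were oxidative phosphorylation (median 0.17) and IL-1 family signalling (-0.17) in the deep libraries alone, the cell cycle (0.20) in the libraries without Y-linked transcripts, NF-κB targets (-0.08) with set a alone, and stress and immediate early genes with library weights (-0.16), with set a alone (-0.61) and without Il1rn-/- 3-b and 4-b (-0.45). The interferon list passed under 32 of 38 settings (adjusted p 3.57e-09 to 0.976) and oxidative phosphorylation under 31 of 38 (9.58e-10 to 0.976). The count for oxidative phosphorylation includes the deep libraries alone, where the direction was opposite. No list call of any setting held with an estimated correlation. For the lists the cause was not tested. Of 4520 values of named genes under alternatives over both sets together, 216 differed in sign from the value reported, and 1 passed (Hspa1b in the shallow libraries, with 0 reads in every wild-type one and 1 in each Il1rn-/- one, too few to read). Within set b, Bora (2.13) and Spg7 (1.49) passed without the intensity trend, Klf3 (-1.53) without Il1rn-/- 1-b, and 20 named genes without Il1rn-/- 2-b. With the replicate number as a block, 0 genes were higher and 0 lower by limma (633 at an unadjusted p under 0.05). The correlations of the 7 numbered pairs were -0.15 to 0 and 0 of 14 libraries correlated best with its own number, so the numbers were not taken to pair the libraries. Tests by edgeR and DESeq2 on recovered reads were not run, and limma voom was run on those reads instead. Low reads limit what can be said of Il1r1 and Tnfsf11.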

Other observations

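The tests that use the library groups or Y-linked transcripts, and the choice of the genes without overlap, were made after the results were seen. Some early-response genes stood higher in the deep libraries that held Y-linked transcripts. The immediate early transcription factor gene Fos differed by 2.12 ± 0.24 log2 (estimate ± SE), Klf6 by 2.37 ± 0.26 and the orphan nuclear receptor Nr4a1, which follows antigen receptor signals, by 1.72 ± 0.17. The activation marker Cd69 differed by 2.44 ± 0.26, the phosphatase gene Dusp1 by 2.23 ± 0.22 and the transcription factor gene Bhlhe40 by 2.42 ± 0.19. Tagap, Dnajb9, Per1, Mafk, Gem and Csrnp1 were also higher, by 1.23 to 2.11, and 3632454L22Rik was lower, by -3.82. These 13 genes outside the sex-linked ones passed in limma at adjusted p-values of 0.00094 to 0.0382. The comparison set 4 libraries with 374 to 808 Y-linked reads (2 wild-type, 2 Il1rn-/-) against 4 deep libraries with 0 each. In Il1rn-/- the deep libraries with these reads were 3-b and 4-b, and those without were 1-a to 3-a. There the comparison is also set b against set a, so the letter cannot be told apart from Y-linked transcripts. In wild type all deep libraries were of set a, and only 3-a lacked these reads. Other early-response genes did not pass, with differences of 0.02 for Egr1, -0.03 for Egr2 and -1.15 for Dusp2. Neither the stress and immediate early list nor the antigen receptor list passed after adjustment over the lists (adjusted exact permutation p 0.225 for both). Xist had 1 to 10 reads in the 4 libraries with Y-linked reads and 236 to 1435 in the other 10.

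Between the genotypes, 4 of 12329 genes had no overlap of the 7 wild-type and 7 Il1rn-/- libraries, where chance gives 0.0583% of genes, or 7.2. They were Rreb1, the angiomotin family gene Amotl1 and the prolyl isomerase gene Fkbp7, all below every wild-type library, and the mitochondrial transcription factor gene Tfam, above. The log2 difference was -2.89 ± 0.71 for Amotl1, -2.86 ± 0.71 for Fkbp7 and 0.23 ± 0.12 for Tfam, and the means of Amotl1 and Fkbp7 were near the lowest values. Of the 6 pairs of libraries with the same genotype and number in sets a and b, 3 differed in Y-linked transcripts, so a shared number did not mark libraries of 1 animal in those pairs.

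Regroupings of the libraries were used to ask whether chance could give as many calls. Where the real grouping gave 0 genes, every split is as large by construction, so these counts decide nothing and chance cannot be excluded. This holds for the genes higher and the genes lower in Il1rn-/- (highest other 1, 100 of 100 splits for each), for set b (highest other 1, 35 of 35) and for the difference between sets (highest other 0, 100 of 100). In set a the 10 splits, all 10 as large, are too few for a share under 0.05 (0 in the real grouping, highest other 0). Chance cannot be excluded for the lists called by camera, where the real grouping gave 2, another split gave 14, and 80 of 100 were as large. It can be excluded for the letter (2408 genes, highest other 19, 1 of 100 as large), but the split by library group gave 4447. For Y-linked transcripts in the deep libraries the real split gave 13 genes outside the sex-linked ones, and another split gave 12. Of the 35 splits 1 was as large, the smallest share they can give, so chance is not firmly excluded there.

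The first pattern weighed was the division into 6 shallow and 8 deep libraries, for which the design names no group, so no biological explanation was tested. Sequencing depth as the cause is argued against, since 82.8% of the genes called between the groups were still called after the deep libraries were thinned to 754025 reads outside Rn45s, the median of the shallow ones. Transcript length and GC content are argued against, with 86.3% still called after correction for both. Reads shared between gene copies may account for part of the pattern, because genes sharing at least 50% of their sequence differed more than genes sharing none, by 0.69 in the median absolute log2 difference (p = 0.001, the smallest that 1000 permutations can give), but not for all of it, because 30.7% of the genes sharing none were called. A difference in library preparation or in the authors' processing between the groups was not tested and stays open.

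The second pattern was the interferon list, whose mean was higher in Il1rn-/- by 0.38, with a 95% interval of -0.05 to 0.82. The unequal numbers of deep libraries are argued against as its source, since the difference was 0.40 with the library group as covariate and the imbalance accounts for -0.02, at most 0.11 by its interval. The libraries with Y-linked transcripts, 2 in each genotype, are argued against as its source too, since the difference was 0.36 with both covariates and they account for 0.05 beside the library group, at most 0.14. In the 10 libraries without such transcripts it was 0.25 (-0.41 to 0.90). Monocytes in the sort are argued against, since their list differed by -0.23 and the interferon list exceeded it by 0.63 (0.14 to 1.12).

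For dendritic cells, which the CD4 and Foxp3-reporter sort is meant to remove, the list differed by -0.18, but the interferon list exceeded it by 0.58 with an interval of -0.23 to 1.40, so they stay open. Their abundant markers Cd74 and H2-Ab1 had mean log2 CPM of 5.58 and 5.01, and 1 of their 11 genes, Bst2, is also in the interferon list. A chance arrangement stays open with an exact permutation p of 0.0798, so a genotype effect on interferon-induced genes is a hypothesis that more libraries could test.

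The third pattern was the early-response genes in libraries with Y-linked transcripts, all 4 of them deep. The stress and immediate early list had means of 6.10 to 6.66 in these and 4.82 to 5.50 in the other 4 deep libraries, a difference of 1.35 with an exact permutation p of 0.0333, the smallest that its 30 arrangements can give. The library group is the same in all 8, so it is argued against as the source of this difference. The lists differed by -0.57 for B cells, -0.37 for monocytes and -0.07 for dendritic cells, each below the stress list by more than its interval, which argues against those cells. For plasma cells, which the sort is also meant to remove, the stress list exceeded their list by 1.4 with an interval of -1.7 to 4.49. That comparison cannot exclude them, but the level of those of their transcripts that were measured argues against them. Of their 10 listed genes 7 were measured, among them Xbp1 at a mean log2 CPM of 6.65. These summed to at most 243 CPM in any deep library and differed by -4.74 CPM (-134 to 125). The stress list gained 7220 CPM (4090 to 10400). Y-linked and Xist reads mark the sex of the cells, but the labels do not give their handling on the day. Sex and handling therefore cannot be told apart. The letter stays open as well, because the deep Il1rn-/- libraries with Y-linked transcripts were of set b and those without were of set a. In wild type the only deep library without these transcripts was 3-a.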
